A study of Rattus norvegicus with 6 samples.

How the data were processed

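Primary cells of the rat temporomandibular joint disc, the fibrous pad between the jaw joint's bones, were compared in 2 groups of 3 samples: cells given the TRPV4 agonist GSK101 and cells given the solvent DMSO, both for 24 h. Per the labels' protocols, total RNA was taken with TRIzol and treated with DNase. Stranded libraries of polyadenylated RNA were made with a kit that marks each cDNA molecule with a unique molecular identifier of 8 random bases. The libraries were sequenced in paired-end mode on a DNBSEQ-T7 instrument. The replicate numbers come from the sample titles, and the sources used here do not say whether replicates came from separate animals, cultures or days. The p-values therefore measure the spread between these samples, which may be partly technical.

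The authors deposited 1 table of RPKM values (reads per kilobase of gene length, scaled to the reads counted in the library) for 20675 rat genes in the 6 libraries, with each gene's chromosome, exon starts and ends, strand and length. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, featureCounts, Subread 1.5.1, edgeR 3.12.1 and the genome build Rnor_6.0, without saying what each was used for or in what order. Whether reads that shared a molecular identifier were collapsed, whether strand was used in counting, and how reads that map to several places were treated is not given in the sources used here. The gene symbols were used as the file gives them, with older symbols of the listed genes matched by hand. All coordinates are those of the file and refer to Rnor_6.0. No genome sequence was used, so GC content was not examined.

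The RPKM values, multiplied by gene length, summed to 1000000 reads per library, so the authors' deposited RPKM values were scaled to the reads counted to genes. In each library these products were whole multiples of a fixed step, to within 0.01 of a read, for 100% of the values. Taking the step as 1 read gave 43061102 to 45705238 counted reads per library. Of the genes with 1 to 10 reads, 71.3% to 74.7% had an even number, so the 2 mates of a pair may have been counted as 2 reads and the number of fragments is then lower than the number of reads. Replicates were compared with a chi-square test on the reads divided by 2, over genes with at least 10 of these in the pair of libraries. Counting noise was otherwise not taken from the reads. A floor of 3 reads served only for reading low values in the text, as for Cxcl2, and no gene was filtered or set to not detected by it. Such floors cover counting error only.

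The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with group as the only term and empirical Bayes moderation with a mean-variance trend. Genes entered the test with an RPKM of at least 0.5 in at least 3 of the 6 libraries, which left 12801 genes. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of genes are from limma. Fold changes on the log2(RPKM + 0.5) scale understate the change of genes with low values, so the ratio of the mean RPKM values is given beside them for such genes. The plan had count models for a file of raw counts. As the file holds RPKM, those were not run, and limma-voom on the recovered reads was added after the data had been seen.

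Fixed before the data were examined were 36 gene lists: pathways, matrix and cartilage genes, signalling components and markers of other cell types a disc culture could hold. Of their 634 members 601 were found in the file and 467 were tested. Lists with at least 3 tested members, 35 in all, were tested against the remaining genes with camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were run beside it. The lists of CXC chemokines, AP-1 genes and p38 MAPK components follow the title of the series, so they are not independent of what the study found on these samples.

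The genes named in the text follow a rule that was also set beforehand. It takes Trpv4, Fos, Cxcl1, Cxcl2, Cxcl3 and Mapk14 whatever their result. It adds the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean RPKM of at least 1 in the higher group, groups that do not overlap and a symbol that is not a clone or locus identifier. From each list it takes up to 4 members with the smallest adjusted p, or up to 2 with the highest mean RPKM where fewer than 2 passed. Some list members are left out of the text, and any other gene named is said to have been chosen after its values were seen.

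The alternatives covered 2 other pseudocounts, 2 other filters, 3 other scalings between libraries, 2 other variance models, the replicate number as a block and leaving out each library in turn. After the data had been seen, limma-voom, the removal of each library's gene length trend with a loess curve (span 0.3) and a camera test of 70 gene families sharing a symbol prefix were added. The bounds for the test of gene length were set before its own outcome was seen. The procedure was tested on simulated data in 10 simulations of 3 against 3 libraries with the real genes' means and library sizes. In each, 200 genes changed by known folds. All genes were given the same dispersion, which was not estimated from the real data. Over about 12819 tested genes, limma called 2.6% of genes changed by 1.25-fold, 32.6% at 1.5-fold, 79.4% at 2-fold and 96% at 4-fold. Of its calls 9.83% were unchanged genes, more than the nominal 5%, against 5.35% for limma-voom. A raised list of 25 genes was called by camera in 100% of the simulations with either correlation. Unchanged lists had p under 0.05 in 2% of cases with the preset and 0% with the estimated correlation. Simulated genes were drawn independently of each other, so these rates do not show how camera performs on correlated genes. In the real data the estimated correlation reached 0.86, for the CXC chemokine list.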

Results

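Gene expression was measured by RNA sequencing in primary cells of the rat temporomandibular joint disc after 24 h with GSK101, an agonist of the calcium-permeable cation channel TRPV4, and in cells given DMSO for the same time. Each group had 3 libraries. The libraries held 43973072 to 45705238 counted reads in the controls and 43061102 to 45293829 with GSK101, and 11352 to 11546 genes reached an RPKM of 1. The 10 most abundant genes took 10.5 ± 0.32% of the counted reads in the controls and 9.51 ± 0.34% with GSK101, with no overlap between the groups. Genes of the mitochondrial genome took 3.21 ± 0.21% and 2.91 ± 0.14%, and ribosomal protein genes 3.16 ± 0.15% and 2.97 ± 0.10% (SD, n = 3), with overlapping values in both cases. The first principal component held 55.5% of the variance and separated the groups. The chi-square per gene was 2.36 to 7.84 for pairs of replicates and 30.1 to 38.1 for pairs across the groups. No pair of replicates agreed within counting noise, and all 6 libraries were counted separately, as the labels give them. Part of the spread between replicates may be technical, since the sources used here do not say whether duplicate reads were collapsed.

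The comparison asked what activation of TRPV4 changed in the transcripts of disc cells. Among genes that met the naming rule, 4 CXC chemokine genes had the largest increases on the log2(RPKM + 0.5) scale and elastin was among the 8 largest decreases. All 25 tested cell cycle genes rose, and 9 of 18 tested YAP and SRF targets fell. Of 12801 tested genes, 2570 were higher and 1518 were lower with GSK101 in the limma test, 31.9% of the genes tested. Most changes were small, with a median absolute log2 fold change of 0.35 among the calls, and 89 genes were at least 2-fold higher and 16 at least 2-fold lower. The groups did not overlap for 4075 of the 4088 calls and for 47.3% of all tested genes, where chance gives 10% for 3 against 3. The share of calls that were higher depended on the scaling between libraries: 62.9% with RPKM as deposited, 72.4% after rescaling to TPM (2936 higher, 1117 lower), 52.7% with median-ratio scaling (2165 and 1947) and 48.1% with quantile normalization (1983 and 2141). The counts of genes changed at least 2-fold moved with the pseudocount, to 151 and 42 at 0.1 and to 56 and 10 at 1. They also moved to 134 higher after rescaling to TPM, to 186 and 49 with limma-voom, and to 25 lower without GSK101 replicate 3.

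Cxcl6, Cxcl13, Cxcl3 and Cxcl1, which encode secreted attractants of leukocytes, had the 4 largest log2 fold changes among genes that met the naming rule. By the ratio of the means, compared only within the 8 largest increases on the log2 scale, Cyp26b1 and Scin lay above Cxcl1. The microRNA row Mir711, with at most 1 read in a control library, is left out of this ranking by ratio. Cxcl1, a neutrophil attractant, went from an RPKM of 4.32 ± 0.56 to 20.4 ± 6.09 (SD, n = 3), a log2 fold change of 2.08 (SE 0.19, adjusted p = 0.000345). Cxcl3 went from 0.275 ± 0.141 to 3.41 ± 1.03, a 12.4-fold ratio of the means and a log2 fold change of 2.31 (SE 0.22). Cxcl6 went from 0.138 ± 0.025 to 4.46 ± 2.74, a 32.4-fold ratio of the means, on 8 to 12 reads per control library and 116 to 516 reads per GSK101 library. Cxcl13, an attractant of B cells, went from 0.130 ± 0.087 to 3.36 ± 1.62, a 25.8-fold ratio on 4 to 12 and 76 to 238 reads, and 42.1-fold without control replicate 1. All 4 genes were higher in each GSK101 library than in each control library. The GSK101 libraries also differed among themselves, with Cxcl6 at 7.13, 4.60 and 1.66 and Cxcl1 at 26.8, 19.6 and 14.6. Cxcl2 had 0 reads in each control library and 4, 4 and 0 reads in the GSK101 libraries, which is near the floor of 3 reads, so no fold change is given (exact two-sided permutation p = 0.4, where 3 against 3 allows no p under 0.1).

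**Figure D1:**
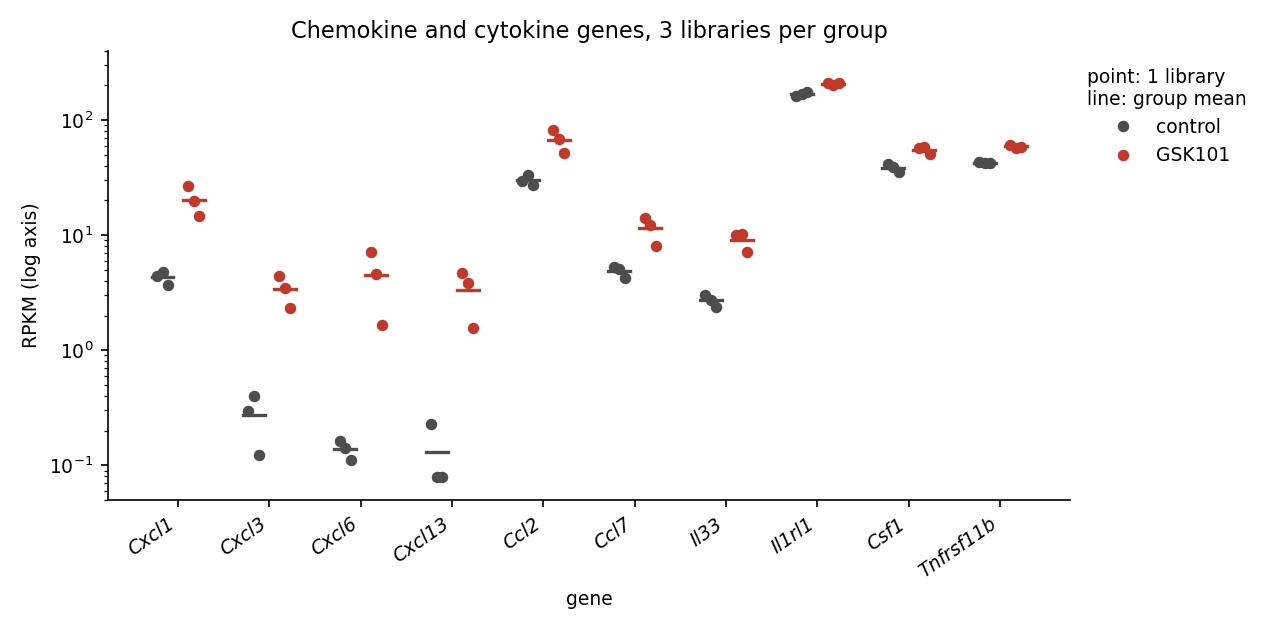
RPKM on a log axis of 4 CXC chemokine genes, 2 CC chemokine genes and 4 cytokine or receptor genes, with a point per library, a line at the group mean, control in grey and GSK101 in red. For Cxcl6 the control libraries lie between 0.112 and 0.162 and the GSK101 libraries between 1.66 and 7.13, while Il1rl1 differs by 1.23-fold between the means.

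On the Rnor_6.0 build, Cxcl1 lies on the minus strand of chromosome 14 from 18743685 to 18745457, Cxcl3 from 18820168 to 18839595 and Cxcl6 from 18860264 to 18862407. Cxcl2 lies beside Cxcl1, from 18731378 to 18733391, and Cxcl13 lies apart on the same chromosome from 15253125 to 15258207. None of the 5 genes shares exon sequence positions with another gene of the file, but the genes are related in sequence. Reads shared between them could not be identified in a table of RPKM values, and only ratios and a sum of their reads were examined. Of the 8 tested genes of the CXC chemokine list 6 rose and none fell, with a median log2 fold change of 1.30. Adjusted over the list alone, 6 rose and 1 fell, as they did over all genes with median-ratio scaling, quantile normalization, the gene length trend removed or limma-voom. The list passed camera (adjusted p = 0.0214) but not with an estimated correlation (adjusted p = 0.98), and the estimate for these genes was 0.86. This list was chosen from the title of the series, so its direction is not independent evidence.

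**Figure D2:**
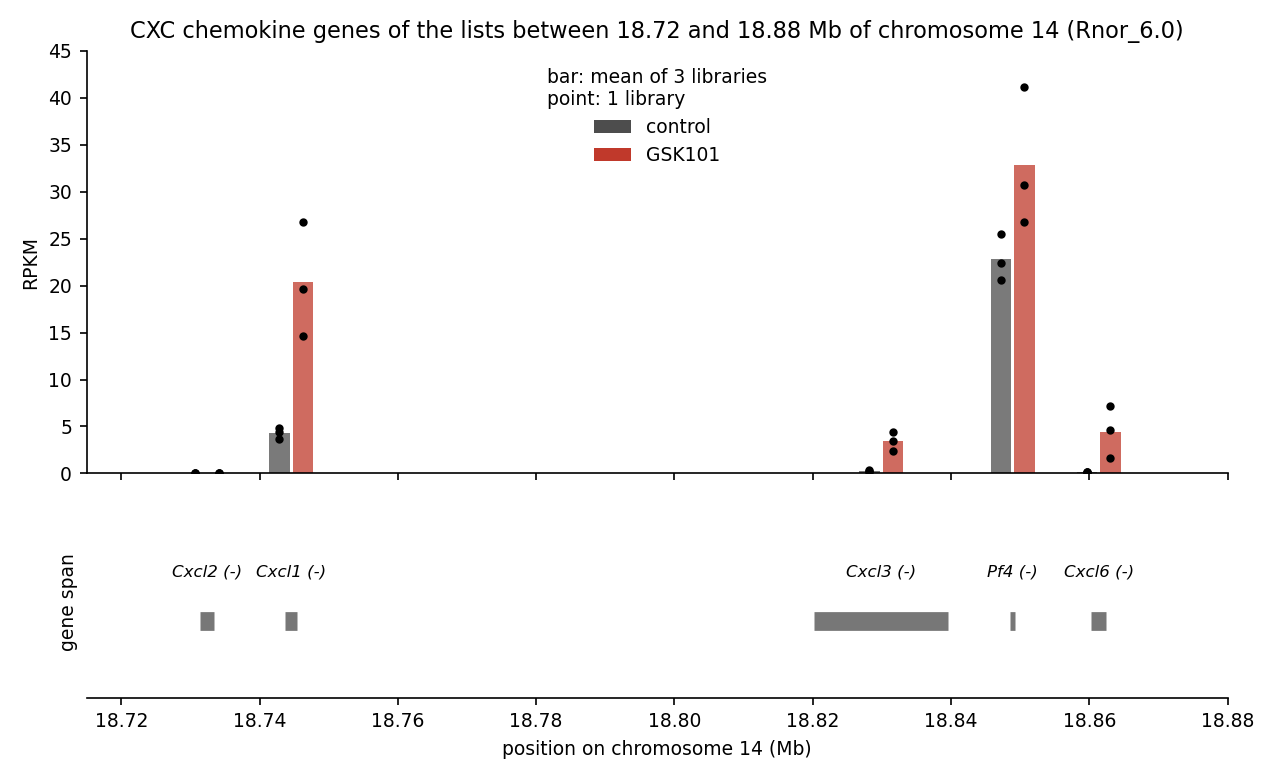
Map of the listed CXC chemokine genes on chromosome 14 of Rnor_6.0 (position in Mb, gene spans as boxes, strand in brackets) below their RPKM, with bars for the mean of 3 libraries from 0 and points for single libraries. Cxcl1 rises from 4.32 to 20.4 beside Cxcl2, which has an RPKM of 0 in the controls, and Pf4, a list member drawn because it lies in this span, goes from 22.8 to 32.9.

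Some chemokine genes of the CC family and some cytokine genes were also higher. Ccl2, a monocyte attractant, rose from 30.04 ± 3.16 to 67.6 ± 14.8 (SD, n = 3), a 2.25-fold ratio with adjusted p = 0.00146, and its neighbour Ccl7 rose 2.36-fold (adjusted p = 0.00311). The third CC chemokine past the threshold was Ccl17, 0.576 ± 0.470 against 2.19 ± 0.967, a 3.80-fold ratio (6.82-fold without control replicate 1) with adjusted p = 0.0222. Its adjusted p lay between 0.0589 and 0.0700 without control replicate 2 or 3 or without GSK101 replicate 1 or 3, and between 0.000807 and 0.0700 over all alternatives. These 3 were the members that rose among 5 tested of the CC and CX3C chemokine list, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.65). Il33, an alarmin of the interleukin 1 family, rose from 2.71 ± 0.31 to 9.13 ± 1.73, 3.37-fold, and Il1rl1, which encodes its receptor, rose 1.23-fold from 168 ± 5.96 to 207 ± 3.63. Csf1, the macrophage growth factor, rose 1.44-fold and Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, 1.39-fold. Il6 rose 1.78-fold, from 4.51 to 8.03, and Il1rn, the interleukin 1 receptor antagonist, 2.01-fold, both chosen here after their values were seen. In all, 6 of the 10 tested inflammatory cytokines and mediators rose and none fell, with 7 higher when adjusted over the list alone. The list passed camera (adjusted p = 0.0052), not with an estimated correlation (adjusted p = 0.56).

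Transcripts of the channel itself were scarce in both groups, and neither they nor those of p38 alpha passed a test. Trpv4, on chromosome 12 from 47698947 to 47737902, had an RPKM of 0.298 ± 0.043 in the controls and 0.295 ± 0.019 with GSK101 (SD, n = 3; 36 to 48 reads per library), below the filter, and no difference was detectable (exact two-sided permutation p = 1). Mapk14, which encodes p38 alpha, had 10.7 ± 0.55 and 10.3 ± 0.60, a log2 fold change of -0.04 with a 95% interval from -0.19 to 0.10. Of the 17 tested p38 MAPK pathway components 1 rose, Zak, a kinase upstream of p38, by 1.69-fold (adjusted p = 0.000262), and 1 fell, Tab2, by 0.16 on the log2 scale. Tab2 lost its call in 11 of the alternatives, among them each of the 6 that left out a library, with adjusted p from 0.0505 to 0.153 in those 6 and from 0.0131 to 0.153 over all alternatives. The list did not pass camera (adjusted p = 0.96), and 1 rose and 0 fell adjusted over the list alone. The counts that rose and fell were 3 and 0 after rescaling to TPM and 1 and 3 with median-ratio scaling or quantile normalization.

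Fos, on chromosome 6 from 109300433 to 109303299, rose from 1.48 ± 0.25 to 3.22 ± 0.55 (SD, n = 3), 2.17-fold, with a log2 fold change of 0.91 (SE 0.14, adjusted p = 0.00239). In the AP-1 family of transcription factors 4 of 12 tested genes rose and 3 fell, with 4 and 4 adjusted over the list alone. Fosl1 rose 1.85-fold (adjusted p = 0.000504), whereas Jund fell by 0.44 and Jdp2 by 0.20 on the log2 scale, and the list did not pass camera (adjusted p = 0.89). The AP-1 and p38 lists, too, follow the title of the series. Of 19 tested immediate early genes outside AP-1, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.71). Nr4a1, an orphan nuclear receptor, rose 2.39-fold, and Gadd45b fell by 0.52 on the log2 scale. Of 16 MAPK feedback regulators 4 rose and none fell (3 adjusted over the list alone, 3 and 3 with quantile normalization, 3 and 1 with median-ratio scaling; camera adjusted p = 0.67), among them Phlda1 and Spry2, by 0.56 and 0.42 on the log2 scale.

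Genes tied to NF-kB and calcium moved in both directions. Of 16 tested NF-kB target and feedback genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.89), with Tnfaip2 1.46-fold higher and Relb and the inhibitor gene Nfkbib lower by 0.39 and 0.40 on the log2 scale. Of 12 calcineurin and NFAT genes 2 rose and 2 fell (3 and 2 adjusted over the list alone, 1 and 3 with quantile normalization, 5 and 2 with limma-voom; camera adjusted p = 0.89). Rcan1 and Rcan2, which encode regulators of calcineurin, fell by 0.45 and 0.70 on the log2 scale, and Ppp3ca, a catalytic subunit of calcineurin, rose by 0.38. Of 15 mechanosensitive and calcium channel genes 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.67). The calcium pump genes Atp2b1 and Atp2b4 rose by 0.43 and 0.71 (Atp2b4 1.88-fold by the ratio of the means), and the calcium release channel genes Itpr3 and Itpr1 rose by 0.93 and fell by 0.39 on the log2 scale, both with exons that overlap an unnamed gene on the opposite strand.

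All 25 tested cell cycle genes rose, also adjusted over the list alone, by 0.46 to 1.24 on the log2 scale with a median of 0.72. Mki67, a marker of proliferating cells, went from 16.1 ± 0.84 to 35.4 ± 0.26 RPKM (SD, n = 3), 2.21-fold, with adjusted p = 8.28e-05. Top2a, a DNA topoisomerase of dividing cells, rose 2.29-fold from 36.5 ± 3.10 to 83.5 ± 3.59. Ccna2, which encodes cyclin A2, and Rrm2, a subunit of ribonucleotide reductase, rose 1.77-fold and 1.76-fold. The GSK101 libraries lay close together, with mean log2 differences of the list from the control mean of 0.77, 0.74 and 0.76. The list passed camera (adjusted p = 1.94e-16), not with an estimated correlation (adjusted p = 0.14).

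**Figure D3:**
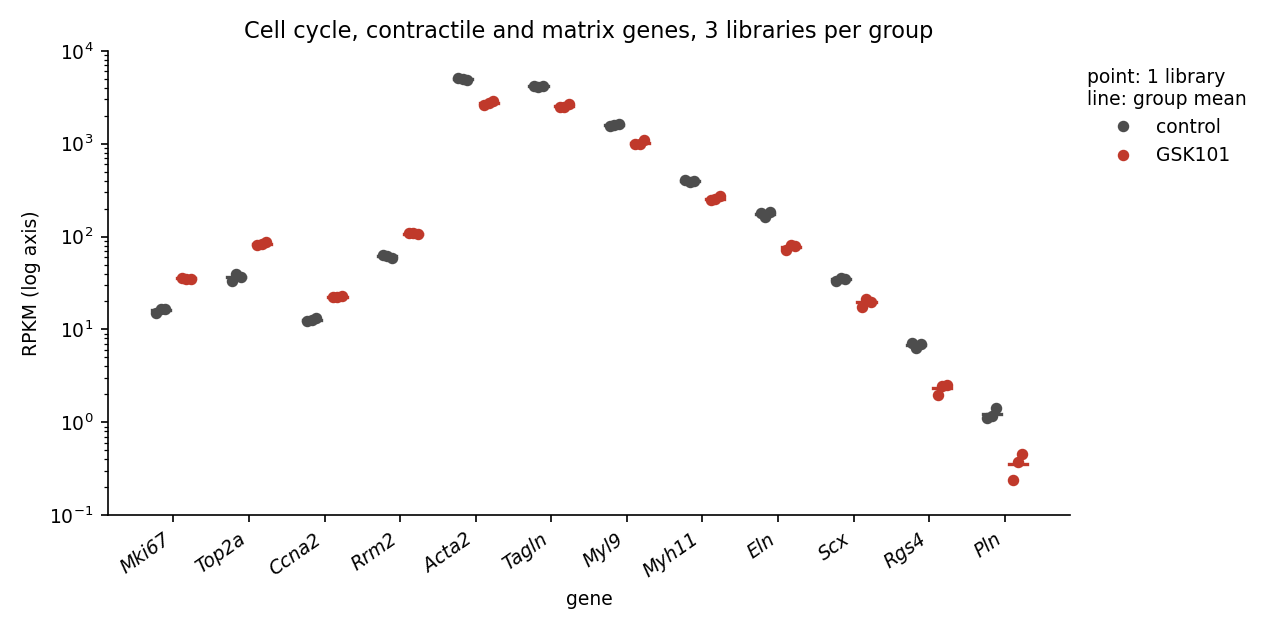
RPKM on a log axis of 4 cell cycle genes and of 8 contractile, signalling or matrix genes, with a point per library, a line at the group mean, control in grey and GSK101 in red. The 3 GSK101 libraries lie above all control libraries for Mki67, Top2a, Ccna2 and Rrm2 and below all of them for the other 8 genes, from Acta2 (4946 against 2734) to Pln (1.23 against 0.355).

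Of 18 tested YAP and SRF targets 9 fell and 1 rose, with 12 and 1 adjusted over the list alone, and the median log2 fold change was -0.27. The list passed camera (adjusted p = 6.95e-06), not with an estimated correlation (adjusted p = 0.48). Acta2, which encodes smooth muscle alpha actin, fell from 4946 ± 105 to 2734 ± 121 RPKM (SD, n = 3), by 0.86 on the log2 scale (SE 0.05, adjusted p = 0.000101). Myl9, a myosin light chain gene, fell by 0.63, from 1581 ± 37.95 to 1021 ± 59.7. Actg2 and Tagln fell by 0.97 and 0.70 on the log2 scale, but their exons overlap those of another gene on the same strand, which makes their levels less certain. These 4 genes, which encode contractile proteins or proteins bound to them, had the smallest adjusted p of the list. Among other actin cytoskeleton genes of the list, chosen here after their values were seen, Cnn1 and Tpm1 fell by 0.46 and 0.33 on the log2 scale. Vcl, Flna and Actn1 did not pass, with log2 fold changes of 0.01, -0.05 and -0.03, and Flna was lower with the gene length trend removed. The remaining members, also chosen after their values were seen, were mixed. Ctgf, Cyr61 and Sdpr fell by 0.52, 0.29 and 0.28 on the log2 scale and Axl rose by 0.23. Ankrd1, Amotl2, Ajuba, Lats2 and Crim1 did not pass, so the falls of the list lay mostly in its contractile genes. Outside the list, Rgs4, a regulator of G protein signalling, was 2.93-fold lower (6.80 ± 0.46 against 2.32 ± 0.32). Pln, which encodes the calcium pump inhibitor phospholamban and is not on the list either, was 3.48-fold lower (1.23 ± 0.17 against 0.355 ± 0.108).

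Of 7 tested markers of pericytes and smooth muscle 5 fell and none rose, also adjusted over the list alone, and 5 fell and 1 rose with limma-voom (camera adjusted p = 0.0206, adjusted p = 0.50 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain gene, fell by 0.63 on the log2 scale from 396 ± 8.73 to 255 ± 13.4 RPKM, and Mcam fell by 0.53. Of 4 tested skeletal muscle markers 3 fell, also adjusted over the list alone: Acta1, Myh4 and Myh3, by 0.65, 0.68 and 0.69 on the log2(RPKM + 0.5) scale and 1.61-fold, 1.88-fold and 3.33-fold by the ratio of the means (camera adjusted p = 0.0257, adjusted p = 0.48 with an estimated correlation). Their levels were low, with Acta1 at 12.4, Myh4 at 2.06 and Myh3 at 0.596 RPKM in the controls, and the log2 fold change of Myh3 ran from -0.44 to -1.73 over the alternatives.

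Matrix genes of the disc changed in both directions. Eln, which encodes elastin and lies on chromosome 12 from 24978483 to 25021863, fell from 174 ± 11.6 to 77.2 ± 4.86 RPKM (SD, n = 3), 2.25-fold, with a log2 fold change of -1.17 (SE 0.06, adjusted p = 9.76e-05). Has2, the hyaluronan synthase gene, rose 2.14-fold from 11.2 ± 0.33 to 24.0 ± 3.21, and Col6a3, a collagen VI chain gene, rose 1.85-fold from 26.2 ± 2.75 to 48.5 ± 3.70. Of the 26 tested fibrous matrix genes 7 rose and 4 fell, with 7 and 6 adjusted over the list alone, but with 5 and 6 under median-ratio scaling, 6 and 7 with the gene length trend removed and 10 and 7 with limma-voom (camera adjusted p = 0.89). Among 18 matrix-degrading proteases 6 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.89). Mmp3, stromelysin, rose 1.98-fold and the aggrecanase gene Adamts5 2.00-fold, while Adamts1 fell by 0.35 on the log2 scale. Of 8 protease inhibitors 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.89). Serpine2 rose 1.43-fold, and Timp3 and Timp2, inhibitors of metalloproteinases, fell by 0.46 and 0.27.

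Cartilage, tendon and growth factor genes were mixed as well. Of 10 tested chondrocyte markers 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.34). Prg4, which encodes the joint lubricant lubricin, rose from 11.0 ± 2.26 to 31.2 ± 9.73 RPKM (SD, n = 3), 2.84-fold, and Cilp fell by 0.99 on the log2 scale from 54.4 ± 3.56 to 27.2 ± 2.95. Of 8 tendon and ligament markers 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.95). The 1 that fell was Scx, the tendon transcription factor scleraxis, by 0.82 on the log2 scale, from 34.7 ± 1.08 to 19.6 ± 1.76. Of 21 TGF-beta and BMP signalling genes 8 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.72). Inhba, which encodes an activin subunit, rose 1.88-fold from 180 ± 11.5 to 338 ± 9.53, and Tgfb3 fell by 0.60. Bmp3, outside that list, was 2.54-fold lower, 7.48 ± 0.57 against 2.94 ± 0.09.

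Of 25 tested genes of the endoplasmic reticulum stress response and ATF4 targets 15 fell and 1 rose, with 15 and 2 adjusted over the list alone, and the median log2 fold change was -0.16. Asns, the asparagine synthetase gene, fell by 0.39 and Trib3 by 0.48 on the log2 scale, from 33.3 ± 0.18 to 25.3 ± 0.76 and from 20.3 ± 0.14 to 14.4 ± 0.88 RPKM (SD, n = 3). The list passed camera (adjusted p = 0.0004), not with an estimated correlation (adjusted p = 0.18), and 9 members fell without GSK101 replicate 1. Of 20 tested genes of the hypoxia and glycolysis list 9 rose and 1 fell, with 10 and 1 adjusted over the list alone. Hk2, Ldha and Pkm, which encode the glycolytic enzymes hexokinase, lactate dehydrogenase and pyruvate kinase, rose 1.71-fold, 1.51-fold and 1.40-fold, and Tpi1, whose exons overlap a gene on the opposite strand, 1.42-fold. That list passed camera (adjusted p = 0.0237), not with an estimated correlation (adjusted p = 0.98). How reads of pseudogene copies of such genes were assigned is not given in the sources used here.

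The other stress and housekeeping lists did not pass camera. Of 15 heat shock genes 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.94), with the small heat shock genes Cryab and Hspb1 lower by 0.58 and 0.50 and Hsph1 higher by 0.46 on the log2 scale. Of 16 oxidative stress genes and NRF2 targets 5 rose and none fell, also adjusted over the list alone, but 1 fell with median-ratio scaling, quantile normalization or the gene length trend removed (camera adjusted p = 0.49), among them Gclc, 1.35-fold, and Srxn1, 1.45-fold. Of 7 histone genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.39). Of 19 p53 targets and senescence genes 3 rose and 1 fell, also adjusted over the list alone, but 2 rose and 4 fell with median-ratio scaling or quantile normalization and 3 and 4 with limma-voom (camera adjusted p = 0.89), with Lmnb1, the lamin B1 gene, 1.67-fold higher. Of 18 cell death genes 2 rose and 2 fell, also adjusted over the list alone, but 5 rose and 1 fell after rescaling to TPM (camera adjusted p = 0.71). Of 19 cholesterol synthesis genes 1 rose and 4 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.67), and of 13 interferon response genes 1 rose and 2 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.72).

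Among markers of other cell types, 1 of 9 tested markers of macrophages and leukocytes rose, Cd14, 1.69-fold from 1.88 to 3.18 RPKM (camera adjusted p = 0.96). The leukocyte markers Lyz2 and Cd68, at 59.8 and 6.01 RPKM in the controls, had log2 fold changes of 0.03 (SE 0.12) and -0.05 (SE 0.22). Of 12 markers of fibroblasts and synovial lining 3 rose and 1 fell (camera adjusted p = 0.89), with Prrx1 1.45-fold and Pdpn 1.31-fold higher. Of 3 osteoblast markers Spp1, which encodes osteopontin, rose 2.02-fold and Alpl, alkaline phosphatase, fell by 0.71 on the log2 scale (camera adjusted p = 0.89). Of 4 endothelial markers Kdr rose by 0.53 (1.84-fold by the ratio of the means) and Erg fell by 0.75 (camera adjusted p = 0.72). Of 6 Schwann cell and neuron markers 1 rose and 1 fell (camera adjusted p = 0.89), and none of 5 adipocyte markers passed (camera adjusted p = 0.89). These 6 lists gave the same counts adjusted over the list alone. Krt8, at 2.09 RPKM in the controls, was the only tested marker of epithelial cells and did not pass over all genes (adjusted p = 0.0962), while adjusted over the list alone, which is then 1 gene, it fell. Over the 35 lists tested, 8 passed camera and none did with an estimated correlation, where the lowest adjusted p was 0.14, while fry called 12 lists for a common direction and 34 for change in either direction. In 8 lists that did not pass camera, among them p38 and NF-kB, the median, the mean and the test differed in sign.

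**Figure D4:**
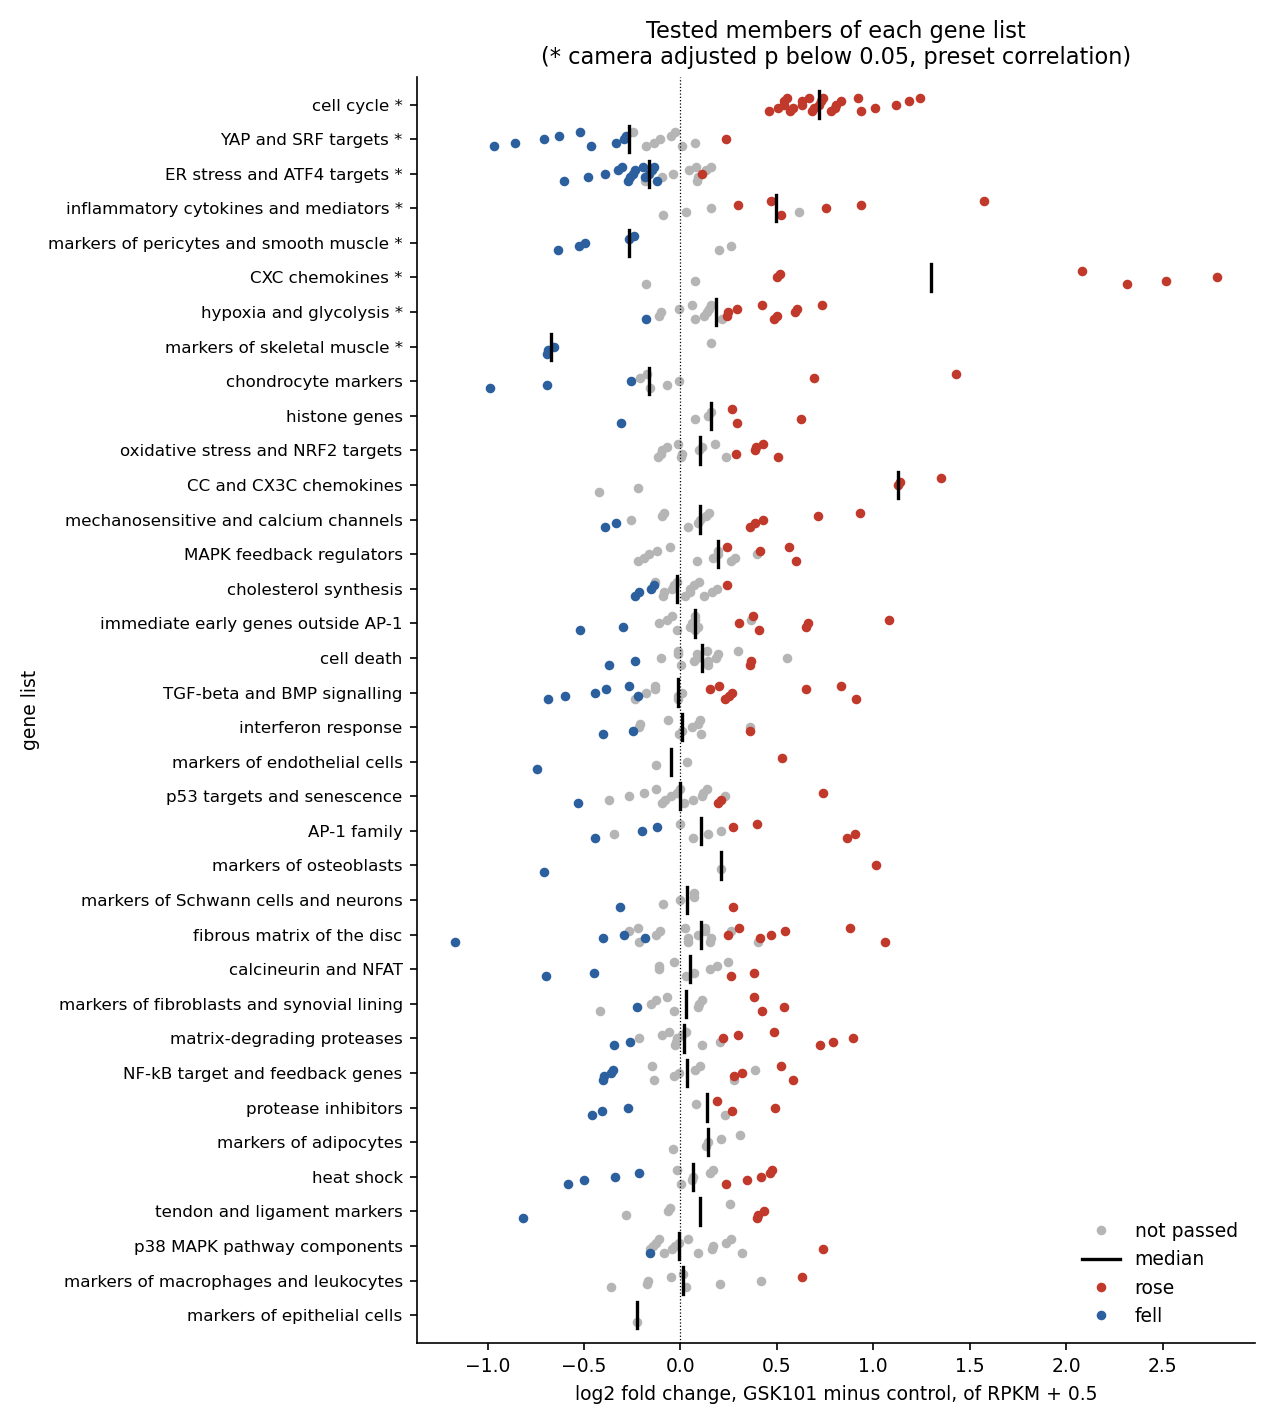
Log2 fold changes of log2(RPKM + 0.5), GSK101 minus control, of the tested members of each gene list, with a point per gene coloured by its call and a black line at the list's median; an asterisk marks the 8 lists past camera. All 25 cell cycle genes lie between 0.46 and 1.24, and 4 CXC chemokine genes lie above 2.

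The remaining genes with the largest changes, like Rgs4, Pln and Bmp3, belonged to none of the lists. Scin, which encodes an actin-severing protein, went from 1.02 ± 0.33 to 5.25 ± 1.52 RPKM (SD, n = 3), 5.13-fold, and Fam25a from 4.79 ± 0.88 to 18.3 ± 4.41, 3.81-fold. Cyp26b1, which encodes a retinoic acid-degrading enzyme, rose 5.86-fold from 0.417 ± 0.076 to 2.44 ± 0.14 (adjusted p = 0.000102). Galnt18, a gene of O-linked glycosylation, was 2.84-fold lower (4.99 ± 0.37 against 1.76 ± 0.25). Parm1 was 2.49-fold lower (24.0 ± 1.24 against 9.62 ± 0.37, adjusted p = 8.28e-05). Nfe2l3, a transcription factor related to NRF2, was 3.43-fold lower (1.40 ± 0.29 against 0.408 ± 0.029). The rule also took the microRNA rows Mir711 and Mir3577, of 68 and 113 bases, which had at most 13 reads in a library and overlap exons of Col7a1 and Tmem94 on the same strand. Their values are uncertain for that reason, and Mir711 lost its call in 8 of the alternatives, with adjusted p of 0.115, 0.123 and 0.0568 without control replicates 1, 2 and 3 and a range of 0.0245 to 0.123 over all alternatives.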

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

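Of these alternatives, limma-voom on recovered reads and the removal of the gene length trend were chosen after the data had been seen. Across the 18 alternatives no call shared with the reported test changed direction, and the number of genes past the threshold ranged from 2890, without GSK101 replicate 1, to 4590, with limma-voom. All 25 cell cycle genes were higher in each alternative, the CXC chemokine list had 4 to 6 genes higher, and the YAP and SRF list 8 to 13 genes lower. The genes at least 2-fold higher, 89 as reported, numbered 151 with a pseudocount of 0.1, 56 with a pseudocount of 1, 134 after rescaling to TPM and 186 with limma-voom. Those at least 2-fold lower, 16 as reported, numbered 42, 10 and 49 with pseudocounts of 0.1 and 1 and with limma-voom, and 15 to 25 when single libraries were left out, with the 25 obtained without GSK101 replicate 3. A smaller pseudocount gives genes of low RPKM larger fold changes, and for the other alternatives the cause was not tested. The ER stress and ATF4 targets that fell, 15 as reported, numbered 9 to 12 when single libraries were left out, with 9 without GSK101 replicate 1, where fewer samples were tested. Of 133 named genes past the threshold 21 lost the call in at least 1 alternative and none reversed. In the lists of p38 components, calcineurin and NFAT, fibrous matrix, p53 targets and cell death the balance of higher and lower calls turned or became uneven under another scaling or limma-voom. It became even for the AP-1 family (4 and 4 with median-ratio scaling or quantile normalization), MAPK feedback regulators and TGF-beta and BMP signalling (3 and 3, 6 and 6 with quantile normalization), and for chondrocyte markers, cholesterol synthesis and the interferon response (2 and 2, 1 and 1, 1 and 1 after rescaling to TPM). It became uneven for NF-kB targets (4 and 5 with median-ratio scaling), protease inhibitors (2 and 3 with median-ratio scaling) and the markers of endothelial cells (1 and 2 with quantile normalization), of Schwann cells and neurons (0 and 1 with median-ratio scaling) and of osteoblasts (2 and 1 with limma-voom). No gene list passed camera with an estimated correlation, while median-ratio scaling and the replicate block ended no camera call. The count models planned for a file of raw counts were not run because the file holds RPKM.

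The replicate numbers shared by the groups were used as a block in 1 alternative, which gave 3945 genes past the threshold against 4088 without it. The deviations of libraries with the same number from their group means had correlations of 0.05, -0.06 and 0.05. Not every library correlated best with its own number. These values gave no sign of pairing over all genes, but so few libraries cannot show that the samples were unpaired. By the mean log2 difference from the control mean, replicate 3 was the lowest of both groups for the CXC chemokine list and the leukocyte markers. The same held for the inflammatory cytokine, AP-1 and ER stress lists. For AP-1 the differences were 0.07, 0.01 and -0.08 in control replicates 1, 2 and 3 and 0.25, 0.15 and 0.04 in the GSK101 replicates. Replicate 3 was not the lowest of both groups for the CC and CX3C chemokine, cell cycle, YAP and SRF or pericyte and smooth muscle lists.

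Depth limits the least abundant genes. Cxcl2, with 0 to 4 reads in a library, and the microRNA rows allow no estimate of size. In simulations with 200 changed genes and the same preset dispersion for every gene, changes of 1.5-fold were called in 32.6% of genes. Whether that rate holds for these data, where more genes passed and the spread of each gene can differ from the preset, was not tested. Among the real calls the median absolute log2 fold change was 0.35.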

Other observations

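The tests of gene families, the removal of the gene length trend, the scaling test of the cell cycle genes, the test of smooth muscle markers and all 3 tests of the chemokine genes were chosen only after the results were seen, while the test of splits was set beforehand. Gene families sharing a symbol prefix were examined in addition to the lists, and 11 of 70 families passed camera with a preset correlation, but none with an estimated correlation, where the lowest adjusted p was 0.21. Of 18 tested Nup genes, most of which encode parts of the nuclear pore, 16 rose and none fell (adjusted p = 5.81e-05, and adjusted p = 0.21 with an estimated correlation). Of 31 Kif genes, which encode kinesin motors, 18 rose and 1 fell, and of 34 Cep genes, mostly of centrosome proteins, 18 rose and 1 fell. Of 32 Ddx genes, which encode RNA helicases, 14 rose and none fell, and of 18 Rad genes, many of DNA repair, 8 rose and none fell. Of 40 Usp genes, of ubiquitin-specific proteases, and of 32 Rbm genes, of RNA-binding proteins, 13 rose and 1 fell in each family (adjusted p = 0.27 and adjusted p = 0.53 with an estimated correlation). Of the ribosomal protein genes 8 of 59 Rpl genes and 6 of 48 Rps genes fell and 1 rose in each family. Of all 12801 tested genes 1518 fell and 2570 rose, so these 2 families differed by few rises more than by many falls (camera adjusted p = 0.73 for both with an estimated correlation). Of 22 Cox genes 5 fell and 1 rose, and of 147 Tmem genes 28 fell and 6 rose. The medians of these 11 families kept their sign under TPM, median-ratio and quantile scaling and with the gene length trend removed, but several sizes and counts moved. With the length trend removed the median of the Kif genes went from 0.26 to 0.14 and that of the Usp genes from 0.17 to 0.09, with 6 Usp genes rising instead of 13, a smaller share than the 2467 of all 12801 genes. Those of the Rpl, Rps and Cox genes went from -0.09, -0.09 and -0.11 to -0.04, -0.04 and -0.06, with 5 Rpl and 3 Cox genes falling. The Tmem genes that fell numbered 18 with the length trend removed or after rescaling to TPM, where 10 rose, and 3 rose with quantile normalization. The Rps genes that fell numbered 15 with median-ratio scaling and 10 with quantile normalization. Rescaling to TPM also brought the medians of the Tmem, Rpl and Rps genes to -0.05 and the falling Rpl and Cox genes to 5 and 3, and quantile normalization brought the medians of the Tmem, Rpl and Usp genes to -0.15, -0.06 and 0.10.

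The GSK101 libraries were more alike in some gene groups than in others. The mean log2 difference of the CXC chemokine list from the control mean was 1.68, 1.39 and 0.91 in GSK101 replicates 1, 2 and 3, that of the CC and CX3C chemokines 0.95, 0.47 and 0.37, and that of the cell cycle list 0.77, 0.74 and 0.76. For the YAP and SRF targets it was -0.32, -0.31 and -0.28. The reads of Cxcl6 per 100 reads of Cxcl1 were 5.10 to 6.42 in the control libraries and 46.7, 41.0 and 19.9 in the GSK101 libraries.

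The split of the libraries into control and GSK101 gave 4088 genes past the threshold, and the highest of the other splits gave 0. It was the only 1 of the 10 splits of 6 libraries into 3 and 3 with as many calls, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, limma called 5481 genes in the real split, where 640 would be expected by chance.

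Cell cycle genes were higher with GSK101, and 2 technical explanations were examined. Genes with longer transcripts tended to be higher, with a median log2 fold change of -0.01 among the shortest 2561 and 0.12 among the longest 2560 tested genes (Spearman correlation across genes 0.18, where genes are not independent replicates). With each library's length trend removed, 25 of the 25 genes were still higher, with a median of 0.70 against 0.72 before. The trend was small beside the list's rises of 0.46 to 1.24, so the count of 25 was all but fixed beforehand. The small size of the trend argues against gene length as the whole cause. With median-ratio scaling, which moves all genes of a library by 1 factor, 25 were higher as well, with a median of 0.68. This scaling moved the median log2 fold change of all tested genes only from 0.03 to -0.002. Beside the smallest rise of 0.46 that is little, so this count, too, was all but fixed beforehand. The small size of the move argues against a shift of scale by a few abundant genes as the whole cause. More dividing cells in the GSK101 samples may account for the pattern, a hypothesis that was not tested because cell numbers and cycle phases were not measured here.

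Of 18 tested YAP and SRF targets 9 were lower and 1 was higher with GSK101 (adjusted p = 0.48 with an estimated correlation). With the length trend removed, 12 of the 18 were lower, against 9 as reported. The 3 added calls were genes of 4076 to 8412 bases, for which removing the trend lowers the fold change, so they say nothing about the cause. Of the 9 reported, 6 were genes of 1104 to 1984 bases, with log2 fold changes from -0.29 (Cyr61) to -0.97 (Actg2) before the removal. They moved towards 0 by only 0.03 to 0.06 (Acta2 at -0.86, SE 0.05, before and -0.80, SE 0.04, after). The other 3 reported genes moved away from 0. All 9 were still called, but with moves this small that was all but fixed beforehand. For the 6 shorter genes the small size of the moves argues against gene length as the whole cause. A smaller share of smooth muscle cells or pericytes could not be told apart from lower expression in the disc cells. Among markers of these cells with a mean RPKM of at least 10 the changes ran from -0.63 (Myh11) to 0.20 (Cspg4, which did not pass). Cspg4 was chosen here after its value was seen, and how much of each marker the disc cells themselves express is unknown. An effect of the agonist on these genes within the same cells may account for the pattern and stays open as well.

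Of 8 tested CXC chemokine genes 6 were higher with GSK101 (adjusted p = 0.98 with an estimated correlation). If leukocytes alone expressed Cxcl1 and their markers, a larger share of them would bring the markers up by about as much as Cxcl1. The median log2 fold change of the 9 tested leukocyte markers was 0.012, with a median absolute deviation, scaled to estimate an SD, of 0.27. Under that condition this argues against a larger leukocyte share as the whole cause. How much of each marker the disc cells themselves express is unknown, and the estimated correlation between these markers was 0.58. The mean log2 difference of these markers from the control mean was 0.27, 0.03 and -0.12 in GSK101 replicates 1, 2 and 3, the same order as for the chemokine lists, and -0.01, 0.15 and -0.13 in the control libraries, so a small part through leukocytes stays open. Reads of Cxcl1 counted to its neighbours would keep the ratios between these genes alike in both groups, but the reads of Cxcl3 and of Cxcl6 per read of Cxcl1 were 2.71-fold and 6.41-fold higher with GSK101. Reads moved between the listed CXC chemokine genes would leave their sum alike, but the summed reads of the 13 genes in the file, scaled to counted reads, were 1.66-fold higher with GSK101 and higher in each GSK101 library than in each control library, which argues against it as the whole cause. How the rise is divided among these genes, and reads shared with genes of similar sequence outside the list, were not examined and stay open. Induction of these genes by the agonist may account for the pattern, as a hypothesis found and examined on the same data. In which cells of the cultures the genes rose was not measured.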
